A study of Mus musculus with 6 samples.

How the data were processed

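RNA was measured by sequencing in OT-I CD8+ T cells of the mouse after 48 hours of culture with ovalbumin peptide and with vehicle, TANs or TAMos, in 2 libraries per group. Per the labels' protocols, RNA was extracted with Trizol, its quality was examined on a Bioanalyzer, and libraries were made with an Illumina TruSeq kit and sequenced on a NovaSeq instrument. Groups and replicate numbers were taken from the labels. The labels give no batch and do not say whether the 2 libraries of a group came from separate cultures or animals. The meaning of the abbreviations TAN and TAMo is not given in the sources used here.

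The deposited values are FPKM per gene and library, which the authors computed from reads counted per gene. Per the submitters' processing notes, CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse build mm10 were used, with no role or order stated. The annotation, the strand setting and the gene length behind FPKM are not given in the sources used here. FPKM is relative to all counted reads of a library, so that a large change in abundant transcripts moves the values of all others. Without strand, reads of a gene and of one that overlaps it on the opposite strand cannot be separated. Genes with near-identical copies, such as ribosomal proteins, mitochondrial genes, guanylate-binding proteins, the Ifi200 and Mx families and granzymes, can share reads, and how these were assigned is not known.

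The table held 25638 genes with unique symbols, and every sample column matched a label. Symbols were matched to GENCODE mouse release 21 on GRCm38, the same assembly as mm10, for 25295 genes, from which coordinates, transcript length and GC content were taken. Depth was read from the steps between low values, within a preset range of step sizes. The mostly even numbers of TAMo replicate 1 leave its depth uncertain. In genes with 1 annotated transcript, 7708 in all, between 98.6% and 99.0% of low values (up to 40 reads) were a whole number of reads within a tolerance of 0.1, and the steps gave between 41.7 and 45.2 M counted reads per library. Over all genes the share was 63.1% to 65.1%, so whole reads could be recovered only in part, and a planned count test on whole reads was not run. At this depth 1 read in a gene of 2 kb is worth 0.0111 to 0.0120 FPKM. Between 10146 and 10198 genes per library had at least 1 FPKM.

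Replicates were compared before they were averaged. Over genes with 1 annotated transcript and at least 20 read pairs in both libraries together, the chi-square of the 2 libraries against counting noise alone, divided by its degrees of freedom, was 2.39 for vehicle (1265 genes), 1.98 for TAN (1265 genes) and 10.2 for TAMo (1319 genes), and the median over genes, relative to that of pure sampling noise, was 1.71, 1.58 and 1.62. Reads were taken as pairs throughout, which the mostly even numbers of TAMo replicate 1 leave uncertain for the TAMo value. No pair held identical values, and each library was counted as 1 replicate. Pearson correlations of log2 values across genes were 0.998, 0.998 and 0.996. The first principal component carried 96.3% of the variance and set both TAMo libraries apart from the other 4, and the second, with 2.09%, separated vehicle from TAN.

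Genes with at least 1 FPKM in at least 2 of the 6 libraries were tested, 10727 in all, on the scale log2(FPKM + 1) and with no further scaling. One limma model (lmFit, contrasts.fit and eBayes with a mean-variance trend) over all 6 libraries gave TAN against vehicle, TAMo against vehicle and TAN against TAMo, with 3 residual and 4.07 prior degrees of freedom. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Without adjustment, 3737, 9332 and 9341 genes had p under 0.05. A log2 change on this scale understates the change of genes near 1 FPKM, whereas a fold in the text is the ratio of the mean FPKM of the groups, with nothing added. A value after ± is the SD over the 2 libraries for FPKM and the standard error for a log2 change. For the median of a list it is a standard error over the member genes, which treats them as independent.

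Gene lists of pathways, T cell states and markers of other cells, 32 in all, were written down in advance, and the 29 with at least 5 tested members were tested with camera of limma at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with a correlation estimated per list. That setting also refers its statistic to the 3 residual degrees of freedom rather than to the number of genes. A call can therefore be lost with it although the members of the list are not more correlated. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. The responses to TAN and TAMo share the vehicle libraries, so their correlation, covariance and overlap were set beside 100 simulations without any changed gene. In these all 6 libraries, those of vehicle included, were drawn anew as noise around the overall mean of each gene.

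Genes were named by rule: 12 fixed genes of T cell function; the 8 largest changes in each direction among called genes with a mean of at least 5 FPKM in the higher group and both libraries of one group above both of the other, without predicted names or receptor segments; and, per list discussed, up to 4 of the largest called changes or else the 2 tested members with the highest FPKM. Lyz2, Csf1r, S100a8 and S100a9, and the genes of the closing observations, lie outside this rule and were named after their values were seen. A few genes that the rule or the closing observations would name, 1 of the fixed genes among them, are not reported here. Groups, comparisons, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

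The alternatives were a pseudocount of 0.1 or 0.5, no filter or a mean of at least 5 FPKM, rescaling to one sum per library (TPM), median-ratio factors, quantile normalisation, a fit of the 2 groups compared, no variance trend, robust variance, the replicate number as a block, a log2 change of at least 1, and each library left out in turn. A further 3 were chosen after seeing the data: reads of mitochondrial genes left out of the total (each FPKM divided by the share of counted reads on other genes, with lengths from GENCODE), a loess trend on GC content and transcript length removed from each library, and limma with voom weights on the reads recovered for genes with 1 annotated transcript. Groups of 2 allow neither a test for outlying samples nor one over other splits of the samples.

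The model was tested on simulated reads with 200 changed genes, 50 per fold size, and a dispersion of 0.002, which was assumed. For TAN against vehicle (10180 genes) it recovered 28 of 50 genes changed 1.25-fold and 45 of 50 changed 1.5-fold, for TAMo against vehicle (10196 genes) 25 and 46, and for TAN against TAMo (10235 genes) 30 and 46, with all 50 at folds of 2 and 4 in each. Of the unchanged genes, 17 of 9950, 17 of 9966 and 9 of 10005 were called. Camera called a list of 30 genes shifted 1.25-fold in each comparison and none of 20 unshifted lists. Genes were simulated independently of each other, so this does not show how often camera calls unshifted lists of correlated genes. The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.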

Results

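OT-I cells are mouse CD8+ T cells whose transgenic T cell receptor recognises a peptide of ovalbumin. They were cultured with this peptide for 48 hours together with vehicle, with cells that the submitters call TANs, or with cells that they call TAMos. Both myeloid populations were isolated from the spleen of mice that carried LLC tumours, a transplanted Lewis lung carcinoma. TANs were sorted as CD11b+ cells with Ly6G and low Ly6C, the surface pattern of neutrophils, and TAMos as CD11b+ cells without Ly6G and with high Ly6C, the pattern of classical monocytes. The T cells were purified again after the culture, and their RNA was sequenced. Each of the 3 groups had 2 libraries. Expression was given for 25638 genes as FPKM, reads per kilobase of gene and per M of counted reads. The steps between low values corresponded to 44.8 and 45.2 M counted reads in the vehicle libraries, 44.9 and 44.8 M in the TAN libraries, and 43.8 and 41.7 M in the TAMo libraries. In TAMo replicate 1, 98.8% of low read numbers were even, against 60.5% to 63.8% in the other 5 libraries. Larger steps lay outside the range searched, so its total may be lower than 43.8 M. The number of independent fragments behind that total is therefore uncertain too.

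The comparisons asked how the transcriptome of peptide-stimulated OT-I cells differed after co-culture with either myeloid population, and how the co-cultures differed from each other. Of the 25638 genes, 10727 reached 1 FPKM in at least 2 libraries and were tested. A principal component that held 96.3% of the variance separated the TAMo libraries from the other 4, and the next, with 2.09%, separated TAN from vehicle. Transcripts of the mitochondrial genome made up 8.15% and 8.34% of all FPKM in the vehicle libraries and 8.07% and 8.21% in the TAN libraries, but 1.20% and 1.32% in the TAMo libraries. The libraries of a group are labelled as separate samples and held no identical values, and each was counted as 1 replicate. The labels do not say whether they came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

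After co-culture with TANs the transcript of interferon-gamma was higher, while 25 of 30 tested interferon-stimulated genes and 20 of 29 genes of the interferon-gamma response fell. As lists, both passed the test with a preset correlation and missed it with an estimated one (adjusted p = 0.0579 and 0.0818 with an estimated correlation). Ifng, the gene of interferon-gamma (GRCm38 chromosome 10, 118441046 to 118445892), rose from 679.8 ± 4.04 FPKM with vehicle to 1136 ± 14.8 FPKM with TAN (SD, n = 2), a log2 change of 0.74 ± 0.025 (SE, limma adjusted p = 2.17e-05). Il17a, the gene of a type 17 cytokine (chromosome 1, 20730905 to 20734496), rose 4.10-fold to 27 ± 0.00135 FPKM (adjusted p = 2.23e-05). Tnfrsf8, which encodes CD30 of the TNF receptor family (chromosome 4, 145267137 to 145315164), rose 5.26-fold to 17 ± 0.560 FPKM (adjusted p = 2.23e-05). Isg15, an interferon-induced ubiquitin-like protein (chromosome 4, 156199424 to 156200818), was 2.70-fold lower, at 23.0 ± 0.175 FPKM against 62.2 ± 1.94 FPKM (adjusted p = 1.01e-05). In all, 1005 genes were higher and 1175 lower with TAN, 20.3% of those tested, and 18 of the former and 6 of the latter changed by at least 1 on the log2 scale.

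Further genes were ranked among those with a mean of at least 5 FPKM in the higher group. Sema4f had a log2 change of 1.69 ± 0.049, Il18r1, a chain of the interleukin-18 receptor, 1.42 ± 0.083, and Emp1 1.246 ± 0.099. Atp2b4, a plasma membrane calcium pump, Ttc39c and Lmna, which encodes lamin A and C, followed with 1.19, 1.18 and 1.14. The largest falls at that level beside Isg15 were those of Iigp1 (-1.29 ± 0.095), Mx2 (-1.21 ± 0.084), Ifi206 (-1.16 ± 0.065), Zbp1 (-0.97 ± 0.044), Mndal (-0.95 ± 0.095) and Slfn2 (-0.93 ± 0.033), which belong to interferon-inducible families, and of the chemokine receptor gene Ccr6 (-0.95 ± 0.088). Below it, Il2 and Mx1 fell by 1.08 and 1.01 on the log2 scale. Mx2 and Ifi206, like Mndal, have close relatives in the genome, so reads shared with them leave their own values uncertain.

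Among the genes fixed beforehand for T cell function, Il2 fell to 0.536 ± 0.206 FPKM from 2.24 ± 0.191 FPKM (adjusted p = 0.00111). Gzmb, the gene of granzyme B, was high in all groups and 1.10-fold higher with TAN, at 4706 ± 35.1 FPKM against 4290.3 ± 30.3 FPKM (adjusted p = 0.0235). Il2ra, the interleukin-2 receptor alpha chain, rose 1.23-fold (adjusted p = 0.000725). The activation marker Cd69 fell by 0.42, Pdcd1, which encodes PD-1, by 0.38, and the cytolytic pore gene Prf1, Tnf and Cd8a by 0.13, 0.18 and 0.13 on the log2 scale, with adjusted p between 0.00124 and 0.039. The calls of Gzmb, Prf1 and Tnf were lost without any 1 of the 4 vehicle and TAN libraries, with adjusted p up to 0.185, 0.11 and 0.191. That of Cd8a was lost without vehicle replicate 2, TAN replicate 1 or TAN replicate 2 (up to 0.127). With no filter on low values the adjusted p was 0.18 for Gzmb, 0.0856 for Tnf and 0.0583 for Cd8a, with no variance trend it was 0.0648, 0.0693 and 0.083 and for Prf1 0.0673, and with quantile normalisation 0.368 for Gzmb, at a log2 change of 0.044, and 0.0584 for Tnf. Tcf7 and the proliferation marker Mki67 did not pass the test, with log2 changes of -0.10 ± 0.033 and 0.023 ± 0.044.

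**Figure D1:**
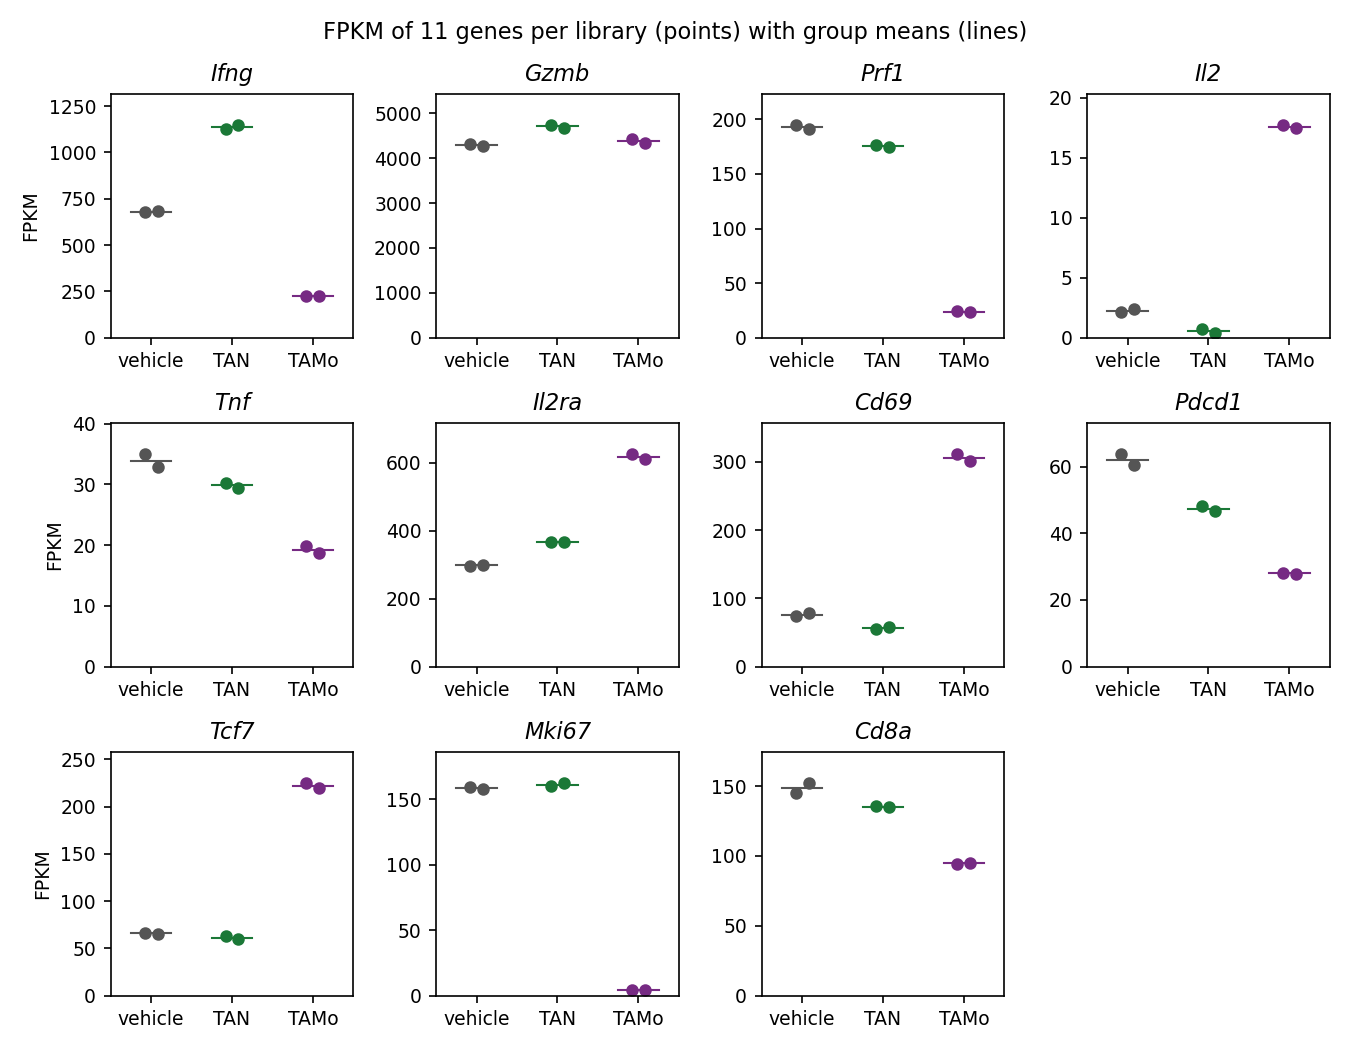
FPKM of 11 of the 12 fixed genes in each of the 6 libraries (points) with the mean of the 2 libraries of a group (lines), on linear axes that start at 0. Mki67 stands at 159 and 161 FPKM with vehicle and TAN and at 4.35 FPKM with TAMo, and Ifng is highest with TAN and lowest with TAMo.

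Of 30 tested interferon-stimulated genes, 25 fell with TAN, none rose and 5 did not pass, with a median log2 change of -0.50 (camera adjusted p = 7.47e-18, adjusted p = 0.0579 with an estimated correlation), and 27 fell when adjusted over the list alone. Mx1, at 1.05 against 3.17 FPKM, was among them. Of 29 tested genes of the interferon-gamma response, 20 fell, 1 rose and 8 did not pass, and the median was -0.24 (camera adjusted p = 4.5e-11, adjusted p = 0.0818 with an estimated correlation); 22 fell and 1 rose when adjusted over the list alone. Examples were the guanylate-binding protein gene Gbp2 (-0.73 ± 0.043), the protease inhibitor gene Serpina3g (-0.77 ± 0.094) and the chemokine gene Cxcl10 (-0.82 ± 0.13), whose call was lost without vehicle replicate 2 (adjusted p = 0.0502) or TAN replicate 2 (0.0604). These falls went along with the rise of Ifng itself.

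Of 27 early activation genes, 15 fell and 3 rose, among them the immediate-early genes Egr1 (-0.82 ± 0.062), Egr2 (-0.59 ± 0.084) and Egr3 (-0.74 ± 0.078), while Cd40lg rose by 0.77 ± 0.087 (camera adjusted p = 8.36e-06, adjusted p = 0.219 with an estimated correlation, 3 rose and 17 fell when adjusted over the list alone). Of 18 cytokine and chemokine genes, 12 fell and 5 rose (camera adjusted p = 0.0441, adjusted p = 0.22 with an estimated correlation, 5 rose and 12 fell when adjusted over the list alone). The chemokine gene Ccl4 fell by 0.76, and Il13 and Il24 rose by 0.77 and 0.93 on the log2 scale. The list missed the threshold without vehicle replicate 1 (0.0521), TAMo replicate 1 (0.0631) or TAMo replicate 2 (0.0625), in a fit of the 2 groups alone (0.0653), with no variance trend (0.0507) and with a trend on GC content and length removed (0.0575). Il24 missed it without any 1 of the vehicle and TAN libraries (up to 0.0835) and with no filter on low values (0.0682). Of 24 genes of the response to interleukin-2 and STAT5, 12 rose and 4 fell (camera adjusted p = 0.00122, adjusted p = 0.22 with an estimated correlation, 14 rose and 4 fell when adjusted over the list alone), with Prdm1 (0.76 ± 0.071), Socs2 (0.68 ± 0.049) and Ikzf2 (0.53 ± 0.064) behind Tnfrsf8.

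Of 40 genes of ribosome biogenesis, 20 fell with TAN and none rose, with a median of -0.13 (camera adjusted p = 3.24e-08, adjusted p = 0.0818 with an estimated correlation, 27 fell when adjusted over the list alone); Ppan fell by 0.42 and Nop2 by 0.32. Of 37 genes of amino acid starvation and the factor ATF4, 18 fell and 1 rose (camera adjusted p = 5.48e-05, adjusted p = 0.22 with an estimated correlation, 1 rose and 20 fell when adjusted over the list alone), with Ddit3 at -0.63 ± 0.091 and Cth at -0.55 ± 0.049. Of 27 genes of the unfolded protein response and heat shock, 6 fell and none rose (camera adjusted p = 0.0215, adjusted p = 0.22 with an estimated correlation, 7 fell when adjusted over the list alone), including the chaperone gene Hspa5 (-0.34 ± 0.028). Of 23 hypoxia genes, 8 rose and 1 fell (camera adjusted p = 0.00549, adjusted p = 0.22 with an estimated correlation, 11 rose and 2 fell when adjusted over the list alone), with Ddit4 at 0.41 ± 0.028 and Hilpda at 0.37 ± 0.043. Replication and mitosis genes gave no list call: 4 of 35 replication genes fell and 2 of 32 mitosis genes, Cenpf and Ccnb2, rose, and camera gave adjusted p of 0.639 and 0.112. Adjusted over the list alone, 2 replication genes fell and no mitosis gene passed. The rises of Cenpf and Ccnb2 were lost without any 1 of the vehicle and TAN libraries (adjusted p up to 0.183 and 0.216), with no filter on low values (0.0713 and 0.0766), with a pseudocount of 0.1 (0.0929 and 0.079) or 0.5 (0.0542 and 0.0616) and with libraries rescaled to one sum (0.0501 and 0.0581). That of Cenpf was also lost with a trend on GC content and length removed (0.0717), and that of Ccnb2 with no variance trend (0.061) and quantile normalisation (0.0572).

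Among lists of cell identity, 8 of 22 T cell identity genes fell and none rose over all genes tested, with a median of -0.081 (camera adjusted p = 0.0125, adjusted p = 0.22 with an estimated correlation, 1 rose and 12 fell when adjusted over the list alone). The largest of these falls was that of Trbv12-1, a T cell receptor beta variable segment, to 125 ± 11.1 from 233 ± 15.1 FPKM. Of 10 tested genes of dendritic cells and MHC class II, 6 fell and 1 rose (camera adjusted p = 0.0105, adjusted p = 0.22 with an estimated correlation, 1 rose and 7 fell when adjusted over the list alone). The invariant chain gene Cd74 fell to 24.3 ± 0.715 from 35.4 ± 0.872 FPKM, and Bst2, also an interferon-stimulated gene, by 0.27. With no filter on low values this list gave an adjusted p of 0.0529. Of 8 genes of CD4 and regulatory T cells, 5 rose and 1 fell (camera adjusted p = 0.0211, adjusted p = 0.22 with an estimated correlation, 5 rose and 2 fell when adjusted over the list alone), led by Cd40lg and by Ctla4, an inhibitory receptor gene, at 729 ± 9.25 against 442 ± 7.72 FPKM. Without vehicle replicate 2 this list gave an adjusted p of 0.0592, and with genes of mean FPKM of at least 5 alone 0.202. Of 40 neutrophil genes, 38 stayed under 1 FPKM in every library. The only one tested was Il1r2, at 1.5 ± 0.156 FPKM with TAN and 0.431 ± 0.259 FPKM with vehicle (log2 change 0.81 ± 0.14), a rise that missed the threshold without vehicle replicate 1, TAN replicate 1 or TAN replicate 2 (adjusted p up to 0.0718) and with no filter on low values (0.0516). The neutrophil genes S100a8 and S100a9 were listed at 0 in the TAN and vehicle libraries.

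The other 17 lists tested did not pass for TAN against vehicle, with camera adjusted p between 0.0981 and 0.996. In 6 of them, NRF2, p53, cholesterol, TGF-beta, glucocorticoid and monocyte genes, the median, the mean and the test differed in sign. The lists of glycolysis, mitochondrial transcripts and mitosis passed without TAMo replicate 1 (camera adjusted p = 0.0276, 0.0389 and 0.0498), and the first 2 also without TAMo replicate 2 (0.0276 and 0.0389). All 3 passed in a fit of the 2 groups alone (0.0274, 0.0358 and 0.0282), and the first 2 with a trend on GC content and length removed (0.0304 and 0.0032), where the median of the mitochondrial list was -0.18. Of 15 cytotoxic effector genes, 5 rose and 6 fell, among the latter the receptor gene Klrk1 (-0.72 ± 0.070). The 12 list calls were all lost with an estimated correlation, for which the smallest camera adjusted p was 0.0579. The estimate lay under the preset 0.01 for some of them, such as interferon-stimulated genes (-0.0054) and ribosome biogenesis (-0.013). For others, such as interferon-gamma response genes (0.022), it lay above. These losses therefore do not show that correlation among members explains the list results, since the test also used only 3 degrees of freedom. The counts of genes rested on all 4 libraries: 358 were higher and 367 lower without vehicle replicate 1, 390 and 439 without vehicle replicate 2, 372 and 451 without TAN replicate 1, and 325 and 405 without TAN replicate 2.

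Co-culture with TAMos gave a far larger response, in which the genes of DNA replication and mitosis fell to a small fraction of their level and targets of the tumour suppressor p53 rose. Plk1, a mitotic kinase (chromosome 7, 122159439 to 122169873), dropped from 139 ± 8.18 to 1.41 ± 0.277 FPKM, a log2 change of -5.87 ± 0.077 (adjusted p = 1.24e-09). Cdkn1a, a cyclin-dependent kinase inhibitor gene and p53 target (chromosome 17, 29090976 to 29100727), rose 34.1-fold from 53.2 ± 0.567 to 1811 ± 12.4 FPKM (adjusted p = 1.75e-10). Tnfsf4, which encodes OX40 ligand (chromosome 1, 161395409 to 161418410), rose by 7.0 ± 0.13 on the log2 scale and reached 259 ± 5.19 FPKM from 1.03 ± 0.0838 FPKM. In all, 4906 genes were higher and 4369 lower with TAMo, 86.5% of those tested, and 1600 and 1543 of them changed by at least 1 on the log2 scale. Without TAMo replicate 1 the counts were 4749 and 4305.

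All 35 tested replication genes fell, with a median of -3.62 (camera adjusted p = 2.06e-14, adjusted p = 0.0496 with an estimated correlation), and so did all 32 mitosis genes, with a median of -4.06 (camera adjusted p = 9.48e-14, adjusted p = 0.0496 with an estimated correlation). The counts were the same when adjusted over the list alone. The replication licensing factor Cdt1 (-5.07 ± 0.058), Uhrf1 (-4.75 ± 0.045), thymidine kinase Tk1 (-4.74 ± 0.052) and Chaf1b (-4.73 ± 0.065) led the former, and Ccnb1 (-5.41 ± 0.044), Cdk1 (-5.31 ± 0.060) and Cdca8 (-4.90 ± 0.033) followed Plk1 in the latter. Espl1, the gene of separase, fell by 5.52. Mki67 went from 159 ± 0.771 to 4.35 ± 0.326 FPKM.

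Of 27 tested p53 targets, 24 rose, 2 fell and 1 did not pass, with a median of 2.43 (camera adjusted p = 1.24e-06, adjusted p = 0.0496 with an estimated correlation, 24 rose and 2 fell when adjusted over the list alone). Trp53inp1 rose from 3.22 ± 0.132 to 214 ± 5.21 FPKM, Phlda3 from 3.77 ± 0.924 to 228 ± 7.67 FPKM, and Zmat3 by 4.50 ± 0.058 on the log2 scale. Ak1 (6.04 ± 0.069), an adenylate kinase gene, Sulf2 (5.98 ± 0.068), Zfp385a (5.22 ± 0.081) and Rgs12 (4.89 ± 0.12) were also among the 8 largest rises of genes with at least 5 FPKM. Vehicle means of Ak1, Sulf2 and Zfp385a lay under 1 FPKM, where the added 1 holds the change down. Of 28 cell death regulators, 16 rose and 9 fell, which gave no list call (camera adjusted p = 0.156, 16 rose and 9 fell when adjusted over the list alone). The death receptor gene Fas rose by 3.91 ± 0.082, the apoptosis inhibitor gene Cflar by 2.24 ± 0.041 and Bcl2l11, which encodes BIM, by 2.18 ± 0.059, and Bcl2a1d fell by 2.05.

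**Figure D2:**
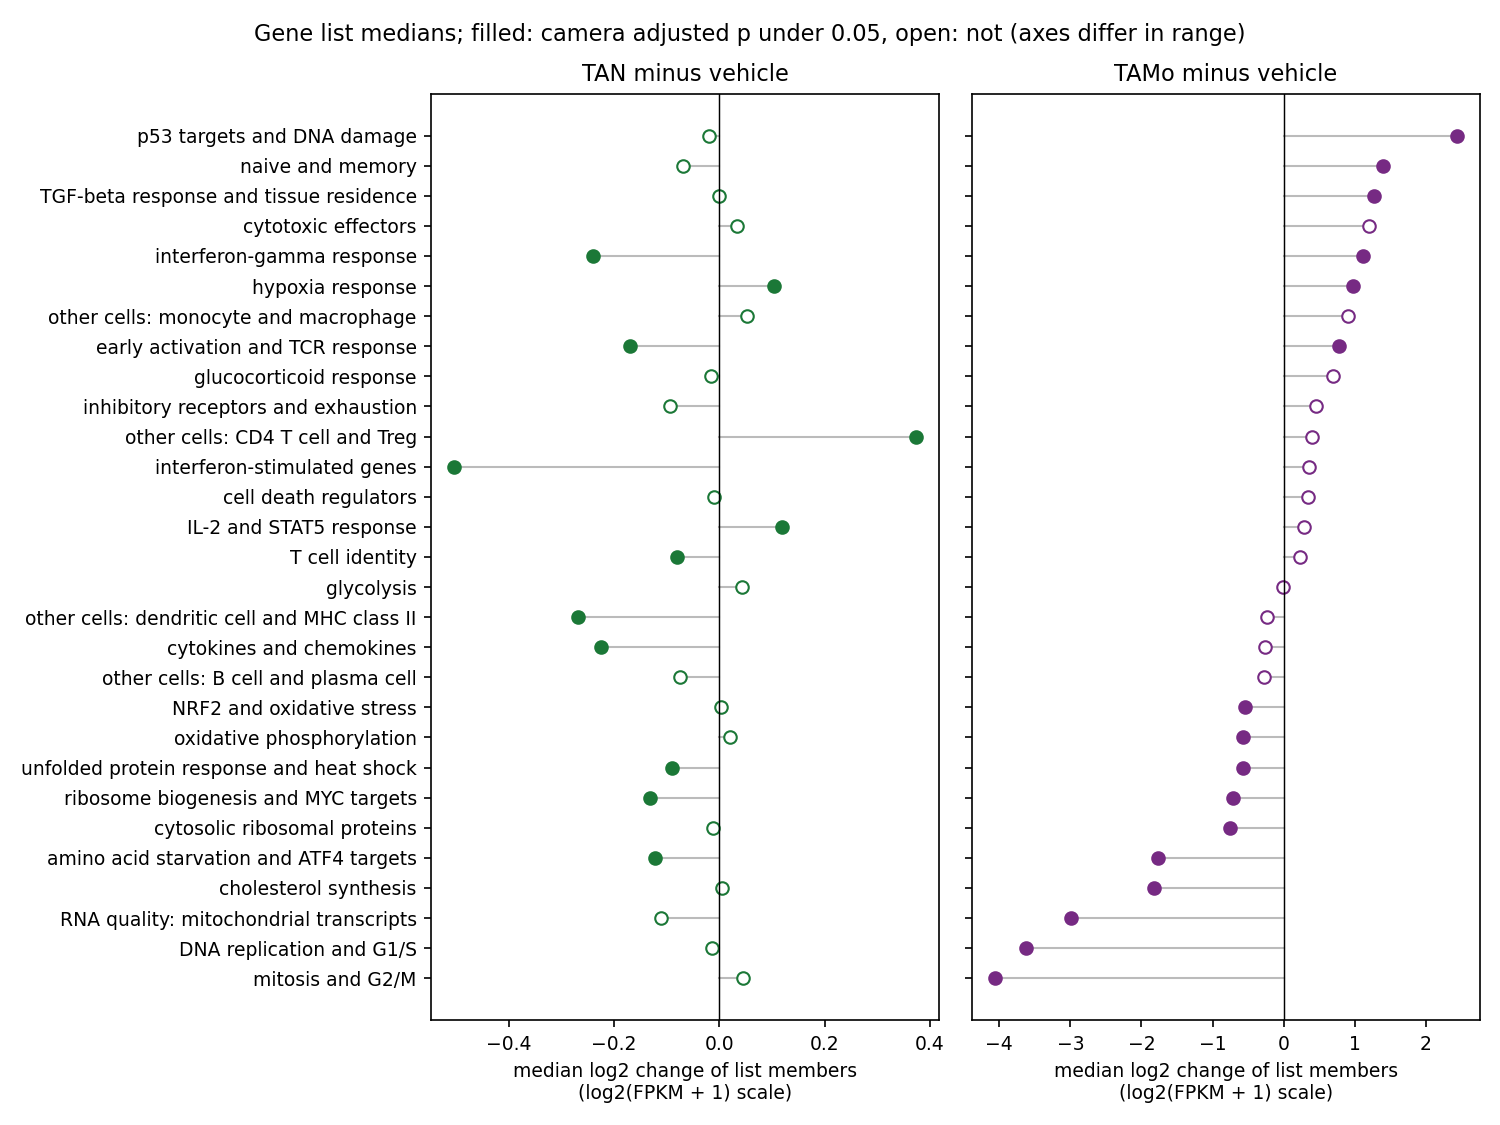
Median log2 change of the tested members of 29 gene lists, on the log2(FPKM + 1) scale, for TAN minus vehicle (left) and TAMo minus vehicle (right), with a different range on each axis. Filled points have a camera adjusted p under 0.05. Mitosis genes lie at -4.06 and p53 targets at 2.43 with TAMo, and interferon-stimulated genes at -0.50 with TAN.

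All 23 tested genes of cholesterol synthesis and uptake fell with TAMo, with a median of -1.83 (camera adjusted p = 1.99e-08, adjusted p = 0.0506 with an estimated correlation, 23 fell when adjusted over the list alone). Acat2 and Cyp51 fell by 3.02 and 2.63 on the log2 scale. Of 37 ATF4 and amino acid genes, 30 fell and 7 rose (camera adjusted p = 5.97e-06, adjusted p = 0.144 with an estimated correlation, 7 rose and 30 fell when adjusted over the list alone). Phgdh, an enzyme of serine synthesis (chromosome 3, 98313170 to 98339990), fell from 543 ± 1.79 to 17.9 ± 0.0706 FPKM, and asparagine synthetase Asns fell by 4.14 and Shmt2 by 3.69 on the log2 scale. Of 40 ribosome biogenesis genes, 33 fell and 6 rose (camera adjusted p = 2.71e-06, adjusted p = 0.0496 with an estimated correlation, 6 rose and 33 fell when adjusted over the list alone), with Nop56 at -2.31 ± 0.025. Of 52 ribosomal protein genes, 46 fell and 1 rose, with a median of -0.75 (camera adjusted p = 3.71e-09, adjusted p = 0.0496 with an estimated correlation, 1 rose and 46 fell when adjusted over the list alone), among them Rpl38 (-1.65 ± 0.084) and Rpl27 (-1.38 ± 0.051). This family has many processed pseudogenes that can share its reads. Of 27 genes of the unfolded protein response, 18 fell and 6 rose (camera adjusted p = 0.0172, adjusted p = 0.138 with an estimated correlation, 6 rose and 18 fell when adjusted over the list alone), with Sdf2l1 at -2.54 ± 0.041 and Edem1 at 2.0 ± 0.031.

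All 13 tested transcripts of the mitochondrial genome fell, with a median of -2.99 (camera adjusted p = 7.76e-06, adjusted p = 0.258 with an estimated correlation, all 13 when adjusted over the list alone). This list was fixed as a sign of RNA quality. Mitochondrial transcripts made up 1.20% and 1.32% of FPKM in the TAMo libraries and 8.07% to 8.34% in the other 4. mt-Nd1, a subunit of complex I, fell from 7585 ± 105 to 845 ± 0.306 FPKM, mt-Nd4 from 1944 ± 35.3 to 243 ± 43.8 FPKM, and mt-Nd3 with a log2 change of -4.0 ± 0.40. Reads of these genes can be shared with nuclear copies of mitochondrial DNA. Of 53 nuclear genes of oxidative phosphorylation, 46 fell and 2 rose, with a median of -0.57 (camera adjusted p = 4.93e-08, adjusted p = 0.0496 with an estimated correlation, 2 rose and 46 fell when adjusted over the list alone). Examples were Uqcrq (-1.59 ± 0.035) and Atp5g3 (-1.38 ± 0.030). Of 23 genes of the oxidative stress factor NRF2, 16 fell and 4 rose (camera adjusted p = 0.0081, adjusted p = 0.138 with an estimated correlation, 4 rose and 16 fell when adjusted over the list alone), with Tkt at -2.13 ± 0.024 and Sod1 at -1.93 ± 0.032. P was 0.0776 with a trend on GC content and length removed. Of 23 hypoxia genes, 17 rose and 4 fell (camera adjusted p = 0.00298, adjusted p = 0.109 with an estimated correlation, 17 rose and 4 fell when adjusted over the list alone), with Ddit4 at 2.60 ± 0.028. Glycolysis genes went both ways, 9 up and 5 down of 23, with a median of -0.0052 and a mean of 0.12 (camera adjusted p = 0.635), so the median, mean and test differed in sign.

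T cell genes moved in both directions with TAMo. Ccr7, a homing receptor of naive and central memory cells (chromosome 11, 99144196 to 99155077), rose 17.3-fold to 3710.4 ± 45.0 FPKM, and the transcription factor gene Tcf7 3.38-fold to 222 ± 3.24 FPKM. Of 20 genes of naive and memory cells, 15 rose and 3 fell (camera adjusted p = 0.00146, adjusted p = 0.109 with an estimated correlation, 15 rose and 3 fell when adjusted over the list alone), with Bach2 at 2.83 ± 0.047 and Ly6c2 at -2.62 ± 0.076. Prf1 fell from 193 ± 2.19 to 23.9 ± 0.409 FPKM and Ifng from 679.8 ± 4.04 to 226 ± 1.63 FPKM. Pdcd1, Tnf and Cd8a fell by 1.12, 0.78 and 0.64 on the log2 scale, with adjusted p of at most 1.93e-06. Il2, at 17.6 ± 0.169 FPKM, Il2ra (1.05 ± 0.025) and Cd69 (1.99 ± 0.041) rose, and Gzmb did not pass (0.034 ± 0.030, adjusted p = 0.319). On other scales Gzmb ranged from -0.058 with mitochondrial reads left out of the total to 0.78 with quantile normalisation, and it passed with the latter (adjusted p = 2.67e-07), with libraries rescaled to one sum (0.00018) and with a trend on GC content and length removed (0.0289).

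Of 15 cytotoxic effector genes, 9 rose and 5 fell (camera adjusted p = 0.187, 9 rose and 5 fell when adjusted over the list alone). Beside the fall of Prf1, Gzmc rose by 2.78 ± 0.090 and Srgn, which encodes the granule proteoglycan serglycin, by 2.18 ± 0.027. Of 27 early activation genes, 19 rose and 7 fell (camera adjusted p = 0.0113, adjusted p = 0.204 with an estimated correlation, 19 rose and 7 fell when adjusted over the list alone), with Dusp5 at 2.24 ± 0.046 and Irf4 at 2.0 ± 0.024. Of 29 genes of the interferon-gamma response, 22 rose and 4 fell (camera adjusted p = 0.000144, adjusted p = 0.109 with an estimated correlation, 22 rose and 4 fell when adjusted over the list alone), including Cd274, which encodes PD-L1 (2.61 ± 0.043), Gbp5 (2.51 ± 0.043) and Icam1 (2.47 ± 0.031). Of 18 genes of the TGF-beta response and tissue residence, 14 rose and 3 fell (camera adjusted p = 0.0081, adjusted p = 0.136 with an estimated correlation, 14 rose and 4 fell when adjusted over the list alone), with Cxcr6 at 3.91 ± 0.11 and Smad3 at 2.58 ± 0.053. Interferon-stimulated genes gave 17 rises and 7 falls among 30 and missed the threshold (camera adjusted p = 0.071, with a median of 0.35), as did the inhibitory receptors (0.442), the interleukin-2 list (0.234) and the glucocorticoid list (0.0707). The interferon-stimulated list passed without vehicle replicate 1 (0.047), with a trend on GC content and length removed (0.0325) and among genes with a mean of at least 5 FPKM (0.00797, with a median of 0.78), and the glucocorticoid list with no filter on low values (0.0319) and with mitochondrial reads left out of the total (0.0465). Cytokines and chemokines had 8 rises and 10 falls among 18 (camera adjusted p = 0.749), with a median of -0.26 and a mean of 0.21, so that median, mean and test differed in sign. Ccl5 rose by 2.70 ± 0.11.

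Of 22 T cell identity genes, 15 rose and 6 fell with TAMo (camera adjusted p = 0.0892, 15 rose and 6 fell when adjusted over the list alone); Cd6 rose by 1.98 ± 0.032 and Cd2 fell by 1.90. This list passed with no filter on low values (0.0384), with quantile normalisation (0.0208) and with a trend on GC content and length removed (0.0173, with a median of 0.41 against 0.22). Trbv12-1 rose from 233 ± 15.1 to 978 ± 33.7 FPKM. Of 45 monocyte and macrophage genes, 33 stayed under 1 FPKM in every library, and of the 11 tested 8 rose and 3 fell (camera adjusted p = 0.149, 8 rose and 3 fell when adjusted over the list alone). The rises included Ms4a4c, to 41.5 ± 2.32 FPKM, Plac8, which was already at 146 ± 1.28 FPKM with vehicle, and Cd14, to 3.01 ± 0.233 FPKM. Lyz2 and Csf1r, abundant in monocytes and macrophages, stood at 0.143 and 0.0162 FPKM in the TAMo libraries. Lists of dendritic, B and CD4 T cells did not pass (camera adjusted p = 0.495, 0.682 and 0.782). The lists of natural killer cells and of erythroid cells and platelets had 2 tested genes each: Gzma rose by 1.49 ± 0.089 and Itga2b by 0.53 ± 0.087, and Eomes and Epor fell by 0.27 and 1.37. The fall of Eomes was lost with libraries rescaled to one sum (adjusted p = 0.141).

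Of the 16 list calls for TAMo against vehicle, 6 held with an estimated correlation: replication, mitosis, p53 targets, oxidative phosphorylation, ribosome biogenesis and ribosomal proteins, all at an adjusted p of 0.0496. FPKM summed to 546324 and 548039 in the TAMo libraries and to between 628328 and 630749 in the others. Rescaling every library to one sum moved the median log2 change of all genes from 0.057 to 0.25, and the share of higher genes among those called from 52.9% to 61.4%. The falls of the ribosomal protein, oxidative phosphorylation and mitochondrial lists kept their sign under every scaling tried.

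TAN and TAMo co-cultures were compared directly in the same model. With TAN, 4356 genes were higher and 4934 lower than with TAMo, and 1529 and 1603 of them differed by at least 1 on the log2 scale. The balance depended on scaling, with 3560 higher and 5757 lower when libraries were rescaled to one sum. With mitochondrial reads left out of the total 4706 were higher and 4532 lower. Ifng was 5.03-fold higher with TAN (log2 difference 2.33 ± 0.025, adjusted p = 6.04e-10) and Prf1 7.37-fold higher, while Il2, Cd69 and Tcf7 were lower by 3.60, 2.41 and 1.84. Gzmb was 1.07-fold higher with TAN (adjusted p = 0.0156), and this direction turned when libraries were rescaled to one sum (-0.10) or quantile normalised (-0.73). The call was also lost without TAN replicate 1 (0.139) or TAN replicate 2 (0.0939), with no filter on low values (0.14) and with a trend on GC content and length removed (0.424). Among the largest differences of genes with at least 5 FPKM in the higher group, Plk1, Ccnb1, Espl1, Cdk1, Fads2, Cdca8, Mki67 and Cdt1 were higher with TAN by 4.87 to 5.87, and Tnfsf4, Ak1, Sulf2, Phlda3, Trp53inp1, Glipr1, Zfp385a and Rgs12 were lower by 4.86 to 7.34. Il1r2 did not differ past the threshold (0.047 ± 0.14).

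Of 29 genes of the interferon-gamma response, 20 had fallen with TAN and 22 had risen with TAMo, list calls lost with an estimated correlation (adjusted p = 0.0818 and 0.109). Their median difference was -1.42, and 26 were lower with TAN and 3 higher (camera adjusted p = 8.53e-06, adjusted p = 0.0789 with an estimated correlation, 3 rose and 26 fell when adjusted over the list alone). Gbp4 stood at 12.2 ± 0.375 FPKM with TAN and 92.0 ± 0.395 FPKM with TAMo. Of 30 interferon-stimulated genes 26 were lower with TAN (camera adjusted p = 1e-04, adjusted p = 0.0668 with an estimated correlation, 4 rose and 26 fell when adjusted over the list alone), and of 27 early activation genes 21 were lower and 5 higher (camera adjusted p = 0.00234, adjusted p = 0.164 with an estimated correlation, 5 rose and 21 fell when adjusted over the list alone). Replication, mitosis, cholesterol synthesis, oxidative phosphorylation, ribosome biogenesis and ribosomal protein genes were higher with TAN and p53 targets lower, and these 7 calls, of 16, held with an estimated correlation (adjusted p = 0.0496 each). The calls for mitochondrial transcripts (higher, adjusted p = 0.271 with an estimated correlation), ATF4 genes (higher, 0.167), NRF2 genes (higher, 0.129), naive and memory genes (lower, 0.101), hypoxia genes (lower, 0.113) and TGF-beta genes (lower, 0.123) did not hold with it. The NRF2 call was also lost with a trend on GC content and length removed (0.0818).

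**Figure D3:**
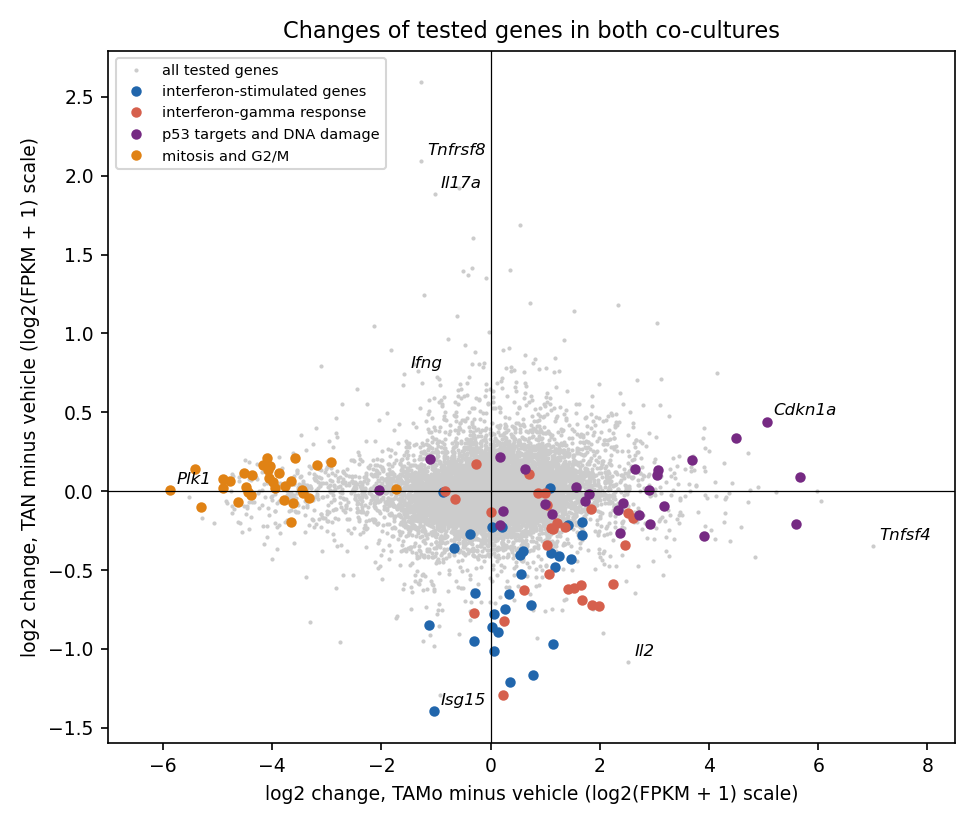
Log2 change of each of the 10727 tested genes on the log2(FPKM + 1) scale, TAMo minus vehicle on the horizontal and TAN minus vehicle on the vertical axis, with members of 4 gene lists in colour. Mitosis genes lie far left, around a median of -4.06, and p53 targets to the right, around 2.43, both near 0 vertically, and interferon-stimulated genes lie below 0, around -0.50.

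Across genes, which are not independent replicates, the log2 changes against vehicle of TAN and TAMo had a Pearson correlation of 0.087. Both comparisons use the same 2 vehicle libraries. Unchanged groups that shared a vehicle group in the same way, with every library simulated, gave 0.50 on average over 100 simulations. That value comes from shared vehicle noise alone, so it gives no baseline for the correlation of 2 real responses. The covariance was 0.0197 against 0.0034 simulated. Higher in both were 621 genes, where 460 came from independent lists of these sizes and 0.05 from simulated unchanged groups, and lower in both were 604, against 479 and 0.09. With no gene changed hardly any is called, so the simulated overlaps are near 0 by construction and give no baseline for 2 real responses. Higher with TAN and lower with TAMo were 281 genes (409 for independent lists), and lower with TAN and higher with TAMo were 451 (537). A split of the vehicle libraries would leave 1 on each side and was not made, so part of the excess may come from them. The counts in both were smaller when either vehicle or either TAN library was left out, as were the counts of genes called with TAN. The overlap of independent lists was not computed for these fits, so they do not show whether the excess shrank.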

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

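The tests of RNA from other cells, of GC content and length, of the mitochondrial share and of nuclear respiratory genes were chosen only after the results had been seen. Those of receptor chains and inhibitors were written down before their values were seen.

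Several results passed the threshold in opposite directions with TAN and with TAMo, and the difference between the co-cultures was tested directly. The median difference of TAN minus TAMo was -0.81 on the log2 scale for early activation genes and -1.42 for interferon-gamma response genes, calls that none of the 3 comparisons kept with an estimated correlation (adjusted p = 0.164 and 0.0789 for the direct difference, 0.219 and 0.0818 for TAN, 0.204 and 0.109 for TAMo). Ifng differed by 2.33, Il2 by -3.60 and Cd69 by -2.41.

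With TAMo, p53 targets rose while replication and mitosis genes fell. RNA of cells other than T cells would lower T cell genes along with mitosis genes. However, the median change of the T cell identity list was 0.22 ± 0.28 (SE over genes) against -4.06 ± 0.18 for mitosis genes. After T cells had been purified, 9 abundant myeloid transcripts had a median of 0.143 FPKM in the TAMo libraries (Cd14 at 3.01 FPKM). The T cell identity list and the myeloid transcripts argue against RNA of cells other than T cells as the whole cause. They cannot detect a share of other T cells, which was not tested as the source. Once a trend on GC content and length was removed, the medians were 2.26 for p53 targets and -4.06 for mitosis genes. The trend held 5.61% of the variance of the changes with TAMo and could hardly have brought these medians near 0. That outcome was therefore set by the small size of the trend. Without mitochondrial reads in the total the p53 median was 2.36. That step moved the median change of all genes only from 0.057 to -0.024. It could not have brought the p53 median near 0, so its outcome was set by the small size of the share. A difference in culture or preparation shared by both TAMo libraries was not tested. A response of OT-I cells to TAMos with p53 activity and a stop of the cell cycle may underlie the pattern, as a hypothesis found on these data. The tests above addressed other causes only, and neither p53 activity nor the cell cycle was measured here.

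All 13 tested mitochondrial transcripts fell with TAMo, by a median of -2.99 ± 0.14 (SE over genes). The estimated correlation among these genes was 0.594, so this SE is likely too small. Their share of FPKM was 1.20% and 1.32% in the TAMo libraries against 8.07% to 8.34% in the others. With the trend on GC content and length removed the median was -2.51. The trend held 5.61% of the variance of the changes with TAMo and could hardly have brought this median near 0. No conclusion was drawn from this step. Nuclear genes of oxidative phosphorylation changed by a median of -0.57 ± 0.085 (SE over genes), which argues against a loss of respiratory genes of both genomes alike. Tfam and Polrmt, which encode proteins of mitochondrial transcription, fell by 0.99 and 0.65, values looked up after the result was seen. Lower mitochondrial transcription in these cells and a loss of mitochondrial RNA during preparation both stay open as possible explanations, and no value here decides between them.

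With TAN, 25 of 30 interferon-stimulated genes and 20 of 29 interferon-gamma response genes fell while Ifng rose, list calls lost with an estimated correlation (adjusted p = 0.0579 and 0.0818). Fewer residual antigen-presenting or B cells would need abundant transcripts of such cells with vehicle, but over 9 transcripts the median was 0.549 FPKM. This argues against such cells as the whole source, since Isg15 fell from 62.2 to 23.0 FPKM. Cst3 was the exception among the 9, at 142 FPKM, and fell by 0.20 on the log2 scale with TAN (limma adjusted p = 0.00944). The B cell genes Cd79a and Cd79b, also among the 9, did not pass (adjusted p = 0.51 and 0.619). A part stays open, since 6 of 10 dendritic cell and MHC class II genes fell too (camera adjusted p = 0.0105, adjusted p = 0.22 with an estimated correlation), Cd74 from 35.4 to 24.3 FPKM. This list shares Bst2 with the interferon-stimulated list, so its fall is not a fully independent sign of fewer such cells. Lower receptor transcripts cannot be told apart from unchanged ones: Ifngr2 changed by -0.19 ± 0.10 (limma adjusted p = 0.23) at 3.76 FPKM, and Ifngr1 rose by 0.23. For inhibitors of interferon signalling the test was also undecided, since 1 of 5 rose where at least 2 or none would have decided it: Socs3 rose by 0.17, a call lost without any 1 of the vehicle and TAN libraries (adjusted p up to 0.182), and Usp18 fell by 0.41. Of these inhibitors, Usp18 is on the interferon-stimulated list, and Socs1 and Socs3 are on the interferon-gamma response list. The inhibitor test was therefore not independent of the falls it was meant to explain. The interferon-stimulated list is not particular to interferon-gamma, and the amount of other interferons was not examined. Its fall therefore need not run against the rise of Ifng. A weaker response to interferon in spite of more Ifng transcript is only a hypothesis, which would need a direct measurement of interferon proteins and signalling.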

How the results depend on the processing

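Leaving reads of mitochondrial genes out of the total, removing a trend on GC content and length, and limma with voom weights on recovered reads were chosen after seeing the data; all other settings were planned. Over all alternatives, 4507 values of named genes kept their direction and their side of the threshold, 103 lost the call, 10 gained it and 11 changed direction; of the list tests these numbers were 1621, 42, 35 and 39. The counts for TAMo against vehicle and TAN against TAMo stayed within 1.5 times under every setting except a log2 change of at least 1, which left 1600 higher and 1543 lower, and 1529 and 1603. For TAN against vehicle it left 18 and 6, and with no filter 644 were higher and 687 lower, and 1198 of the 2180 calls were shared. Across left-out libraries the TAN counts ranged from 325 to 1188 higher and from 367 to 1387 lower, where the lone sample of a group is assumed to vary like the other groups and fewer libraries estimate the spread. With an estimated correlation, and with it 3 degrees of freedom in the test, the list calls fell from 12, 16 and 16 to 0, 6 and 7. The correlation of both responses was 0.0737 with a pseudocount of 0.1, 0.0756 with quantile normalisation and 0.0732 with the GC and length trend removed, and 0.0816 to 0.106 across left-out libraries. Genes in both responses numbered 365 (higher) and 347 (lower) with no filter, 398 (lower) without a variance trend, and 202 to 646 and 160 to 752 across left-out libraries. Apart from the fewer samples and the effect size, the cause was not tested.

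Direction changed almost only for values near 0. For these lists the test changed direction and the value is the median log2 change, with no call in either direction. For TAN against vehicle, cytotoxic effectors had 0.016 with no filter, -0.094 at a mean of 5 FPKM, 0.040 with quantile normalisation, 0.026 with the GC and length trend removed and 0 to 0.069 across left-out libraries. For p53 targets these were -0.041 with no filter and -0.030 to -0.010 across libraries. Cell death regulators had -0.010 with a pseudocount of 0.1, -0.0059 on the TPM scale, -0.0016 with median-ratio factors, -0.0047 with quantile normalisation and -0.020 to 0.0052 across libraries. Cholesterol genes had 0.013 with no filter, 0.0044 with 2 groups and -0.0035 to 0.023 across libraries. TGF-beta genes had 0.00018 at a mean of 5 FPKM and without a variance trend, and -0.017 to 0.0032 across libraries. B cell genes had 0.024 with no filter, -0.056 with the GC and length trend removed and -0.0745 to -0.0034 across libraries. That trend also turned cytokines (0.089) and dendritic cell genes (0.16) for TAMo against vehicle. For TAN against TAMo, cytokines turned with no filter (-0.028) and on the TPM scale (-0.25), dendritic cell genes with no filter (0.028), at a mean of 5 FPKM (0.049) and across libraries (-0.11 to -0.040), glycolysis (0.045) and dendritic cell genes (0.0081) without mitochondrial reads, and CD4 T cell genes at a mean of 5 FPKM (-0.31). Among genes, Mki67 with TAN was at -0.032 with the GC and length trend removed, and Gzmb with TAMo at -0.031 with median-ratio factors and -0.058 without mitochondrial reads. Gzmb for TAN against TAMo was at -0.10 on the TPM scale and -0.73 with quantile normalisation, both called. Il1r2 for TAN against TAMo was at -0.085 on the TPM scale, -0.27 with the GC and length trend removed and -0.071 to 0.17 across libraries. Acly with TAMo was at 0.18 on the TPM scale, which was called, and at -0.047 to 0.0079 across libraries.

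With the replicate number as a block (replicate block), 963 genes were higher and 1177 lower for TAN against vehicle, 4897 and 4385 for TAMo against vehicle, and 4368 and 4932 for TAN against TAMo. Deviations of same-numbered libraries correlated at 0.0567, 0.0245 and 0.0078, the labels do not say that numbers mark a shared origin, and no pairing was assumed. For TAN against TAMo the lists of the unfolded protein response and of T cell identity missed the threshold in the planned analysis and passed in 7 and 8 settings, among them the block (adjusted p = 0.0481 for both), and the glucocorticoid list passed with no filter (0.0243) and with the GC and length trend removed (0.0416). With TAN against vehicle the block gave a call to Tcf7 (adjusted p = 0.0441) and ended those of Cdt1 (0.0588), Cenpf (0.0545) and Rora (0.0602), and changed no other call of a gene or list.

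Rescaling to one sum called 5750 higher and 3615 lower genes with TAMo. Mitochondrial genes took 6.88% to 7.08% of counted reads in the vehicle and TAN libraries and 0.884% and 0.979% in the TAMo libraries, and leaving these reads out of the total moved the median change of all genes with TAMo from 0.057 to -0.024. Log2 changes with TAMo had a Spearman correlation of -0.14 with GC content and 0.27 with length over 10638 genes, and removing the trend took away 5.61% of their variance. On 974 genes with recovered reads, voom called 80 higher and 83 lower with TAN, of which 72 and 77 were among the 92 and 90 called on FPKM, and 418 and 361 with TAMo, of which 416 and 359 were among 437 and 369. A count test on whole reads of all genes was not run, because 63.1% to 65.1% of low values over all genes came out whole. Genes with fewer than 2 libraries at 1 FPKM were left out by choice of the filter, not for lack of depth, and the mostly even read numbers of TAMo replicate 1 leave its sampling error uncertain.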

Other observations

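The genes in this part were chosen after their values or those of related genes had been seen, and the tests of the wider type 17 and fatty acid gene sets were written down before the values of their members were seen.

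Beside Il17a, further genes of type 17 T cells were higher with TAN. Il17f, a cytokine gene related to Il17a, went from 2.35 ± 0.956 to 6.09 ± 0.825 FPKM (SD, n = 2; log2 change 1.11 ± 0.18, limma adjusted p = 0.00834), and Il22 from 2.65 ± 0.166 to 5.30 ± 0.532 FPKM (0.79 ± 0.11, adjusted p = 0.00504). The call of Il17f was lost without TAN replicate 1 (adjusted p = 0.0632) or with no filter (0.0543). Ccr6, a chemokine receptor gene also used by type 17 cells, moved the other way, with a log2 change of -0.95. Of 9 further type 17 genes only 3 could be tested, and 66.7% of these rose: Il23r by 0.86 and Rora by 0.25, whereas Stat3 was at -0.016 (adjusted p = 0.689). The call of Rora was lost without any 1 of the 6 libraries (adjusted p up to 0.176). Of 8 genes of CD4 and regulatory T cells, 5 rose with TAN too (median 0.37, camera adjusted p = 0.0211; adjusted p = 0.22 with an estimated correlation), Cd40lg by 0.77, while Cd8a fell by 0.13, a call lost without any 1 of 3 of the 4 vehicle and TAN libraries (adjusted p up to 0.127), and Trbv12-1 went from 233 to 125 FPKM. Trav14-1, a T cell receptor alpha variable segment, did not change past the threshold with TAN (0.084, limma adjusted p = 0.7). It also did not differ between TAN and TAMo (adjusted p = 0.24), whereas Trbv12-1 was 7.83-fold higher with TAMo than with TAN. Trbv12-1 alone is therefore no measure of the share of OT-I cells. A share of other T cells was not tested as the source, so whether the type 17 transcripts belong to OT-I cells stays open, and 3 tested genes leave a wider type 17 programme undecided.

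With TAMo, most of a set of fatty acid synthesis and desaturation genes were lower. The desaturase genes Scd1 and Fads2 fell from 34.7 ± 0.602 and 53.8 ± 0.776 FPKM to 0.666 ± 0.0994 and 0.404 ± 0.0583 FPKM, with log2 changes of -4.42 and -5.29. Of 10 other genes of the set 9 fell, or 90.0%, where 4369 of all 10727 tested genes fell, and no enrichment test was made beyond this share. Fads1 fell by 3.22, Acaca, the gene of acetyl-CoA carboxylase, by 1.89, and Fasn, the gene of fatty acid synthase, by 1.69. The exception was Acly (-0.019 ± 0.029, adjusted p = 0.551), which on other scales ranged from -0.22 with the trend on GC content and length removed to 0.18 with libraries rescaled to one sum. Lower expression of fatty acid synthesis genes as a group is therefore a hypothesis about transcripts, and it says nothing on lipid synthesis itself.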
